A study of Mus musculus with 16 samples.

How the data were processed

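Single-cell RNA libraries had been made from the lumbar dorsal root ganglia of 16 mice, with 6 ganglia and 1 mouse per library. Cells were freed with collagenase and trypsin and cleared of myelin with magnetic beads, per the labels' protocols. All libraries were made with the 3' v3 expression kit, per the labels' protocols. Reads were processed with Cell Ranger 3.1.0 and Seurat 3.1.1 against GRCm38 (mm10), per the submitters' processing notes. The values are the UMI counts per gene and barcode that the authors deposited, as whole numbers with no normalization. The filtered matrices held 28422 barcodes and 52636 genes, of which 52403 gene identifiers were found in the annotation and 97 symbols belonged to more than 1 identifier.

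The genotype labels gave 4 groups. The global knockout group (7 mice) carried floxed Scn9a and a tamoxifen-inducible Cre under the pCAAG promoter, and its control group (5 mice) lacked the Cre. The cLTMR-specific knockout group (2 mice) carried Slc17a8 Cre, and its control group (2 mice) lacked it, with 1 control mouse carrying 1 floxed allele. Replicate numbers follow the order of the records. Library numbers in the titles fall into 4 runs. Runs 1 to 3 held both groups of the global arm, while run 4 held global knockout replicates 6 and 7 and all 4 libraries of the other arm. The comparisons, tests, gene lists, marker lists and the rule for naming genes were fixed before the data were examined, as were all alternatives except those said to be chosen later.

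Cells with at least 500 detected genes and at most 20% mitochondrial UMIs were kept (19800). Doublets were called per library with the scrublet method in scanpy 1.11.5 and removed. It marked 94 cells (0.47%), from 3 of 2762 in global knockout replicate 6 to 9 of 416 in global control replicate 1. The caller therefore cannot be relied on across these libraries, and doublets may remain. The remaining 19706 cells were log-normalised and clustered (3000 variable genes, 50 principal components, 15 neighbours, Leiden resolution 1 with leidenalg 0.10.2), and 16822 neurons were clustered again at resolution 1.5. Scn9a, Penk, sex-linked, mitochondrial, ribosomal and haemoglobin genes were left out of the clustering. Clusters were named from the fixed marker list with the highest mean score, so class names are rebuilt and may differ from those of the study. A name needed a positive score, at least 3 detected markers and no other list with more markers among the 10 leading genes. It also needed an own marker among those genes, or at least 2/3 of its markers raised and detected in at least 5% of cells. Of 39 neuron clusters, 30 received a name, and 2286 neurons (13.6%) stayed unnamed. The class of C-fibre low-threshold mechanoreceptors (cLTMR) is called cLTMR-like, and the class named from Mrgprd, Lpar3 and related markers is called Mrgprd-type.

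UMI counts were summed per library and class, keeping libraries with at least 10 cells of the class. Genes were tested with the edgeR 4.0.16 quasi-likelihood test (TMM scaling, filterByExpr, robust fit, all 4 groups in 1 fit with sex as a covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. The Schwann cell fit had no sex term, because the design with sex was not of full rank. In the fits with run as a block, run replaced sex as the covariate. DESeq2 1.42.0 was run as a second tool. Gene levels are TMM-scaled CPM unless said to be unscaled, which is CPM over all UMIs of the class in a library. The SD is between libraries, and log2 fold changes carry their standard error. Adjusted p-values are from edgeR unless another test is named. All tests were two-sided unless stated. Penk and Scn9a were also tested by exact permutation of log2(CPM + 1) over all splits of the global-arm libraries.

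The gene-naming rule took Scn9a and Penk in every tested class, and up to 10 genes per direction with the lowest adjusted p per arm and class. It left out predicted genes from the text. From each fixed list it took up to 4 members per class that passed adjusted over the list alone, or the 2 members with the lowest unadjusted p where none did. Slc17a8, Th, Calca and Tac1 in cLTMR-like neurons were always taken. Genes named outside this rule are said to be so. The lists covered opioid peptides and receptors, sodium, potassium and calcium channels, sensory transduction channels, neuropeptides, nerve injury response, immediate early genes, activity-regulated genes, pruritogen and nociceptor receptors, synaptic vesicle release, cLTMR identity, cholesterol synthesis, interferon response, inflammatory cytokines, satellite glia activation, myelin, heat shock and dissociation stress, mitochondrially encoded genes, and RNA of glia and of blood in other cells. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation), with adjustment over lists.

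The fit was tested on simulated data for the global comparison in cLTMR-like neurons, with 6217 genes and 200 of them changed. It recovered 65% of the genes changed 2-fold and 97% of those changed 4-fold, with 10 false calls. The changed genes were drawn only from those above a minimum mean count, and each gene's spread was set by the trend over gene levels. Recovery of scarcer genes, of genes with more spread, in other classes and in the cLTMR-specific arm was not simulated. Shares of cells with a UMI were taken after thinning each cell to 750 UMIs and leaving out shallower cells. Intervals and floors (3 counts at 95% confidence) cover counting error only. Alternatives covered scaling, tool, count filter, covariates, run, sex, cell filter, doublets, clustering, class assignment and leaving out each library. The sex-linked genes matched the labelled sex in 16 of 16 libraries.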

Results

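Gene expression was measured in single cells of mouse lumbar dorsal root ganglia after deletion of Scn9a, which encodes the sodium channel Nav1.7. The global arm compared 7 mice carrying a tamoxifen-inducible Cre with 5 littermates lacking the Cre, and both groups were taken 4 weeks after tamoxifen. Mice of the global arm were older than those of the other arm. The cLTMR-specific arm compared 2 mice carrying Slc17a8 Cre with 2 mice lacking it. Slc17a8 encodes the glutamate transporter VGLUT3. Total counts per library ranged from 650411 to 11622338 UMIs in the global knockout, 842787 to 6325092 in its control, 933192 to 3358631 in the cLTMR-specific knockout and 1494151 to 48035265 in its control. The cells kept numbered 8224, 2729, 2402 and 6351 in those groups. Neurons in unnamed clusters made up 17.4% ± 16.2 (SD, n = 7) of neurons in the global knockout, 9.96% ± 4.36 (n = 5) in its control, 12% ± 0.983 (n = 2) in the cLTMR-specific knockout and 14.3% ± 7.65 (n = 2) in its control. Global knockout replicate 5 stood at 53.9%, and without it the difference between the global groups fell from 7.47 to 1.39 points.

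The targeted gene, Scn9a (ENSMUSG00000075316, GRCm38 chromosome 2, 66480080 to 66634962, minus strand), was detected at similar levels in knockout and control libraries. In cLTMR-like neurons Scn9a stood at 276, 296, 384, 282, 312, 407 and 470 CPM in global knockout replicates 1 to 7, and at 241, 340, 270, 302 and 366 CPM in control replicates 1 to 5 (single libraries unscaled, here and below). It stood at 391 and 363 CPM in cLTMR-specific knockout replicates 1 and 2, and at 534 and 496 CPM in their controls. The log2 fold change of Scn9a was 0.22 ± 0.15 (SE, adjusted p = 0.488) in the global knockout and -0.38 ± 0.25 (adjusted p = 0.493) in the cLTMR-specific knockout. Over all neurons it was 0.14 ± 0.14 (adjusted p = 0.818) and -0.28 ± 0.23 (adjusted p = 1). The assay counts 3' ends and the labels do not name the deleted exons. A 3' tag outside the deleted part checks nothing, so these counts neither verify nor question the genotype labels.

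Penk, the gene for proenkephalin, the precursor of the enkephalin opioid peptides, was much higher in cLTMR-like neurons of both knockouts. Penk (ENSMUSG00000045573, GRCm38 chromosome 4, 4133531 to 4138819, minus strand) averaged 286 ± 68.6 CPM in the global knockout (n = 7, 1689 UMIs) against 3.44 ± 3.73 CPM in control (n = 5, 8 UMIs), a log2 fold change of 6.76 ± 0.37 (adjusted p = 3.12e-15). All 7 knockout libraries lay above all 5 controls. Penk averaged 565 ± 294 CPM in the cLTMR-specific knockout (n = 2, 233 UMIs) against 2.14 ± 2.51 CPM in control (n = 2, 3 UMIs). The ratio of levels pooled over UMIs there was 861, with a counting interval of 291 to 4210 (adjusted p = 1.83e-14). It rests on the deep control replicate 1, at 0.368 CPM against 4.03 in control replicate 2. The log2 fold change of Penk was 9.34 ± 0.54, and 7.27 without control replicate 1. Within runs 1, 2 and 3 the Penk difference was 6.21, 7.17 and 6.22 on the log2 scale. The exact permutation test in the global arm gave p = 0.00126 (0.00631 adjusted over 5 classes), the smallest value the splits can give.

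**Figure D1:**
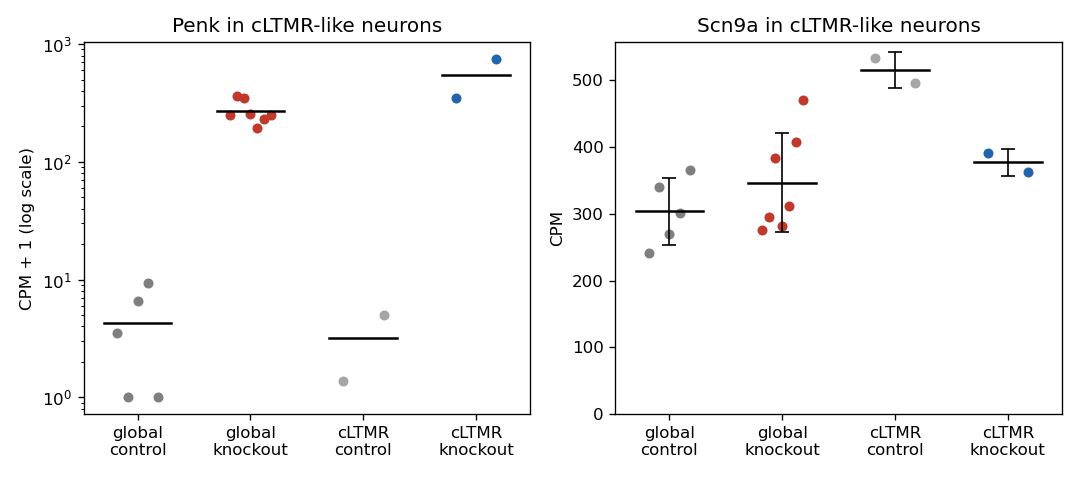
Penk (left, unscaled CPM + 1 on a log axis) and Scn9a (right, unscaled CPM) in cLTMR-like neurons, 1 point per library, with group means as lines and SD bars for Scn9a. Penk lay between 191 and 361 CPM in the 7 global knockout libraries and at 8.38 CPM or lower in the 5 controls.

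Clusters 4 and 16 held most cLTMR-like neurons of the knockouts, and clusters 6, 22, 26 and 33 most of those of the controls. The stress genes Cdkn1a and Phlda3 were among the leading genes of clusters 4 and 16, with no cLTMR marker among the 10 leading genes of either. These clusters took the name through their share of raised markers, 7 of 9 in cluster 4 (score 0.259) and 8 of 9 in cluster 16 (score 1.015). The score of cluster 4 was the lowest of the 30 named neuron clusters. The markers Th, Fam19a4 and Slc17a8 were each among the leading genes of some of the control-rich clusters. The class held 1188 cells of the global knockout, 469 of its control, 376 of the cLTMR-specific knockout and 623 of its control. Every value given for cLTMR-like neurons is over all of these clusters together.

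Penk values were low in the 4 other neuron classes tested in the global arm, while neurons of the Trpm8 class, not tested, carried it in control mice. In Mrgprd-type neurons Penk averaged 2.21 ± 2.45 CPM in the global knockout (n = 7, 27 UMIs) and 0.634 ± 1.06 CPM in control (n = 5, 2 UMIs). The ratio of pooled levels was 5.28 with a counting interval of 1.33 to 45.8, and the exact permutation p was 0.22. In Mrgpra3-type neurons it was 0.205 (7 UMIs against 0), in Sst/Nppb-type neurons 0.0606 (8 against 0) and in peptidergic C nociceptors 0.576 (9 against 4). Over all neurons the log2 fold change of Penk was 1.69 ± 0.7 (adjusted p = 0.474) in the global knockout and 3.88 ± 1.13 (adjusted p = 1) in the cLTMR-specific knockout. The exact permutation test over all neurons of the global arm gave a Penk difference of 2.71 on the log2 scale (p = 0.0126), and without the cLTMR-like neurons it gave -0.06 (p = 0.953). Of the Penk UMIs in those remaining neurons, the Trpm8 class held at least 96 of 176 in the knockout and 112 of 143 in control. That class made up 0.189% to 6.58% of neurons in control libraries. The -0.06 therefore depends on how many Trpm8 neurons were captured and does not show Penk unchanged in each other class. The test of the difference between classes used log2 Penk in cLTMR-like neurons minus that in the remaining neurons of the same library. This difference was 5.21 ± 0.89 in the knockout (n = 7) and -1.34 ± 3.22 in control (n = 5), and the exact permutation test gave p = 0.00126. For Scn9a it was 0.44 ± 0.23 and 0.42 ± 0.21 (exact permutation p = 0.838). In the cLTMR-specific arm the Penk difference was 6.26 ± 0.17 in the knockout and -1.61 ± 0.5 in control (n = 2 each).

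The share of cLTMR-like cells with a Penk UMI, after thinning to 750 UMIs per cell, was 15.2% ± 3.27 (n = 7) in the global knockout and 0.904% ± 0.986 (n = 5) in control (exact permutation p = 0.00126). The share was 27.4% ± 10.0 in the cLTMR-specific knockout (n = 2), and 0 of 584 cells had a Penk UMI in control, which allows a share of up to 0.514%. Shallower cells left out numbered 57, 43, 27 and 39 in the 4 groups. Without thinning the Penk shares were 40.8%, 1.64%, 36.5% and 0.474%. Background in Mrgprd-type neurons, thinned alike, was 0.354% ± 0.656 in the global knockout and 0.0694% ± 0.155 in control. Median depth per neuron was 2066 UMIs in the global knockout and 2681 in control, each a median over libraries. The median over cLTMR-like cells of a library ranged from 1029 to 25375 UMIs in the knockout and from 946 to 26032 in control. A Scn9a UMI was found in 22.4% ± 5.15 and 21.8% ± 3.44 of thinned cLTMR-like cells in the global arm (exact permutation p = 0.824). In the cLTMR-specific arm the Scn9a shares were 23.2% ± 2.26 and 31.2% ± 1.2. Unthinned Scn9a shares were 58.0%, 55.6%, 37.2% and 62.9%, and the thinned share in non-neuronal cells was 1.44% ± 2.4 in the global knockout (n = 4) and 0.258% ± 0.447 in control (n = 3).

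Many genes besides Penk changed in cLTMR-like neurons of the global knockout. Of 6601 genes tested, 584 passed, 307 higher and 277 lower. The increases with the lowest adjusted p after Penk were in Tmem233, a transmembrane protein gene (log2 fold change 4.19 ± 0.26), and Epha5, an ephrin receptor. Epha5 had 621 UMIs in the knockout and 2 in control, a ratio of 156 with a counting interval of 43.0 to 1290. Kcnc4, a voltage-gated potassium channel, rose by 4.10 ± 0.34. Basp1, a growth cone protein, rose by 4.00 ± 0.28, and Mrgpra2b, an itch-type receptor, by 5.16 ± 0.45. Cd44 (2.22 ± 0.2), Emp3 (2.46 ± 0.23), Lmo4 (3.38 ± 0.32) and Tagln2 (1.84 ± 0.16) rose as well. The decreases with the lowest adjusted p were in Mbp, a myelin protein gene (-2.40 ± 0.21), Ceacam10 (-2.39 ± 0.21), Hebp2 (-1.97 ± 0.19) and Pcp4, a calmodulin-binding protein (-2.52 ± 0.2). Gpx2 (-2.24 ± 0.23), Necab3 (-1.75 ± 0.18), Fermt2 (-1.45 ± 0.16), E2f1 (-2.37 ± 0.27), Cd151 (-1.49 ± 0.17) and AC107851.1 (-2.15 ± 0.22) also fell. With library run as a block 925 genes passed, and with male libraries alone 367.

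Several of the class's identity genes fell and several peptide genes rose. Th, the rate-limiting enzyme of catecholamine synthesis, averaged 522 ± 66.9 CPM in the global knockout (n = 7) against 1030 ± 136 CPM in control (n = 5), a log2 fold change of -0.98 ± 0.15 (adjusted p = 8.99e-06), with -0.81, -1.18 and -0.95 within runs 1 to 3. Slc17a8 changed by -1.73 ± 0.34 (adjusted p = 0.00222), with 6 of 7 knockout libraries below all controls. Tac1, the substance P precursor, rose by 1.02 ± 0.17 (adjusted p = 5.74e-05), with 1.46, 1.35 and 0.7 within runs 1 to 3. Calca, the gene for calcitonin and CGRP, rose by 0.76 ± 0.19 (adjusted p = 0.00744), with 1 of 7 knockout libraries above all controls. Th and Slc17a8 were among the markers by which the class was named. Ceacam10, Gpx2, Rgs5, Cd34 and Fam19a4 were also among the leading genes of its control-rich clusters, and Tagln2 and Cmtm8 among those of cluster 4, so the clustering and the changes in these genes are not independent.

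Of the fixed lists, 7 of 20 passed camera in cLTMR-like neurons of the global knockout. All 4 tested opioid genes rose, adjusted over the list alone and over all genes: Penk, Pcsk2, a proprotein convertase (3.34 ± 0.34), Cpe, a peptide-processing carboxypeptidase (1.07 ± 0.13), and Oprl1, the nociceptin receptor (1.71 ± 0.54). The opioid list gave adjusted p = 5.68e-10, and adjusted p = 0.000712 with an estimated correlation. Of 13 nerve injury genes, 12 rose and 1 fell adjusted over the list alone (7 and 1 over all genes), among them the transcription factor Jun (2.61 ± 0.27), Gadd45a (1.37 ± 0.23), the growth cone protein Gap43 (2.92 ± 0.41) and Flrt3 (2.07 ± 0.4). That list gave adjusted p = 6.19e-11, and adjusted p = 0.018 with an estimated correlation. Of 7 neuropeptide genes, 5 rose adjusted over the list alone (4 over all genes), among them Cartpt (3.12 ± 0.57) and Nts, neurotensin (1.64 ± 0.47). The neuropeptide list gave adjusted p = 5e-04, and adjusted p = 0.018 with an estimated correlation. Of 11 cLTMR identity genes, 8 fell adjusted over the list alone (7 over all genes), among them Rarres1 (-1.17 ± 0.14) and the neurturin receptor Gfra2 (-0.72 ± 0.14). That call (adjusted p = 1.31e-06) gave adjusted p = 0.103 with an estimated correlation. The identity list holds all the markers by which the class was named, Rarres1 and Gfra2 included. Its fall is therefore not independent of the naming, and cells wrongly given the name could lower it too.

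The other 3 calls were also lost with an estimated correlation. The myelin list was called downward (adjusted p = 0.00642; adjusted p = 0.0521 with an estimated correlation), with Mbp and Pmp22 (-0.84 ± 0.12) passing among 4 tested, adjusted over the list alone. Both genes are also abundant in Schwann cells, and the glial RNA list gave adjusted p = 0.0524. Pruritogen and nociceptor receptors gave adjusted p = 0.0367 (adjusted p = 0.261 with an estimated correlation). Of 8 tested, 3 rose and 3 fell adjusted over the list alone (3 and 2 over all genes), with the itch receptor Mrgpra3 at 5.00 ± 0.54, Gfra1 at 4.65 ± 0.73 and Lpar3 at 2.92 ± 0.52. Sensory transduction channels gave adjusted p = 0.0478 (adjusted p = 0.166 with an estimated correlation). In that list 4 genes rose and 1 fell adjusted over the list alone (3 and 0 over all genes), with the ATP-gated channel P2rx3 (3.1 ± 0.44), Trpa1 (1.52 ± 0.31) and Asic2 (0.63 ± 0.23) among those that rose. The median of this list was -0.05 and its mean 0.63.

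The remaining lists did not pass camera in this comparison. Sodium channels gave adjusted p = 0.477, with Fgf13 at 1.0 ± 0.15. Potassium and HCN channels gave adjusted p = 0.872, with 4 members higher and 4 lower adjusted over the list alone. Calcium channels gave adjusted p = 0.108, with the T-type channels Cacna1i (-1.65 ± 0.24) and Cacna1h (-1.42 ± 0.28) lower. Synaptic vesicle release gave adjusted p = 0.107, with Cplx2 at -1.99 ± 0.24 and Syt4 at 1.54 ± 0.18. Immediate early genes gave adjusted p = 0.133, with Fos at 1.97 ± 0.55, and activity-regulated genes 0.872, with Nptx1 at -2.42 ± 0.36. Interferon response gave 0.107, with Ifi27 at 0.63 ± 0.17. Cholesterol synthesis gave 0.455, with Sqle at 0.69 ± 0.2. Satellite glia activation gave 0.903, with Glul at -0.95 ± 0.18. Heat shock and dissociation stress gave 0.872, with Hspa1a at -0.96 ± 0.3, mitochondrially encoded genes 0.108, with mt-Atp8 at -0.63 ± 0.3, and blood RNA 0.107, with Hba-a1 at -1.99 ± 1.36. The members named in this paragraph apart from Hspa1a, mt-Atp8 and Hba-a1 passed adjusted over the list alone. Inflammatory cytokines had fewer than 3 members tested in this class and gave adjusted p = 0.759 over all neurons.

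In the cLTMR-specific knockout 387 of the 6601 genes passed in cLTMR-like neurons, 211 higher and 176 lower. Tmem233 rose by 6.24 ± 0.41, Epha5 by 5.36 ± 0.46, Pcsk2 by 4.67 ± 0.46 and Basp1 by 4.56 ± 0.4. Cmtm8 (4.99 ± 0.53), the thrombin-related receptor F2rl2 (4.50 ± 0.48) and the kinase Camk2a (3.73 ± 0.42) rose too. Mrgpra3 rose by 6.42 ± 0.66. Mrgpra2b had 42 UMIs against 3 in control, a ratio of 155 with a counting interval of 49.6 to 783. Th fell from 861 ± 310 to 108 ± 36.3 CPM (n = 2 each), a log2 fold change of -2.85 ± 0.29 (adjusted p = 1.29e-08). Slc17a8 changed by -4.05 ± 0.77 (adjusted p = 0.00238), with 5 UMIs in the knockout. Only the knockouts of this arm carried the Slc17a8 Cre, so an effect of the Cre itself on Slc17a8 counts cannot be told apart. Ceacam10 had 2 UMIs in the knockout and 924 in control, and its control level was 41.7 times the knockout level, with a counting interval of 11.5 to 345. Fxyd6 (-2.36 ± 0.26), Necab3 (-3.31 ± 0.38), Mbp (-4.05 ± 0.49), Rgs5 (-3.45 ± 0.4), Cd34 (-4.42 ± 0.54), Hebp2 (-3.93 ± 0.5), Id4 (-2.83 ± 0.37) and Pde1c (-4.54 ± 0.61) also fell. Tac1 rose by 1.61 ± 0.28 (adjusted p = 0.000175), while Calca stood at -0.20 ± 0.35 (adjusted p = 0.859). All 4 libraries of this arm were in run 4. The count depended on single mice: without knockout replicate 1 it was 113, without knockout replicate 2 it was 235 and without control replicate 1 it was 132. It was 150 with classes assigned by marker score and 816 with run as a block.

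Of the fixed lists, 4 of 20 passed in this comparison. Opioid genes rose, 4 of 4 adjusted over the list alone and 3 over all genes (adjusted p = 5.34e-07; adjusted p = 0.00358 with an estimated correlation). Among 11 cLTMR identity genes 9 fell adjusted over the list alone and 7 over all genes, including Fam19a4 at -1.86 ± 0.28 and Zfp521 at -1.87 ± 0.35 (adjusted p = 4.91e-12; adjusted p = 0.0394 with an estimated correlation). Fam19a4 and Zfp521 were also among the markers that named the class, so here too the fall is not independent of the naming. Nerve injury genes, 8 higher and 1 lower of 13 adjusted over the list alone (6 and 1 over all genes), gave adjusted p = 0.000312, and adjusted p = 0.154 with an estimated correlation. Synaptic vesicle genes, 3 higher and 7 lower of 19 adjusted over the list alone (2 and 5 over all genes), gave adjusted p = 0.045, and adjusted p = 0.431 with an estimated correlation.

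The changes in cLTMR-like neurons of the 2 knockouts overlapped. Among genes passing in both, 146 were higher in both against 9.8 expected if independent, 122 were lower in both against 7.4, and 0 went opposite ways. Of the 584 genes of the global knockout, 564 (96.6%) had the same sign in the cLTMR-specific knockout. Across the 6601 genes the log2 fold changes had Pearson r = 0.66 and Spearman rho = 0.46. Genes are not independent replicates, and the 2 arms have separate controls. In the test of the difference between the knockouts 2 genes passed (401 at an unadjusted p under 0.05), Th and Gm7271, which lies outside the naming rule and was chosen after its values were seen. The log2 fold change of Th in the global knockout minus that in the cLTMR-specific knockout was 1.88 (adjusted p = 0.0068). Without cLTMR-specific knockout replicate 2 no gene passed in edgeR, and Th stood at 1.59 (adjusted p = 0.521). With classes assigned by marker score no gene passed either, but 41 passed with run as a block and 48 with no count filter.

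**Figure D2:**
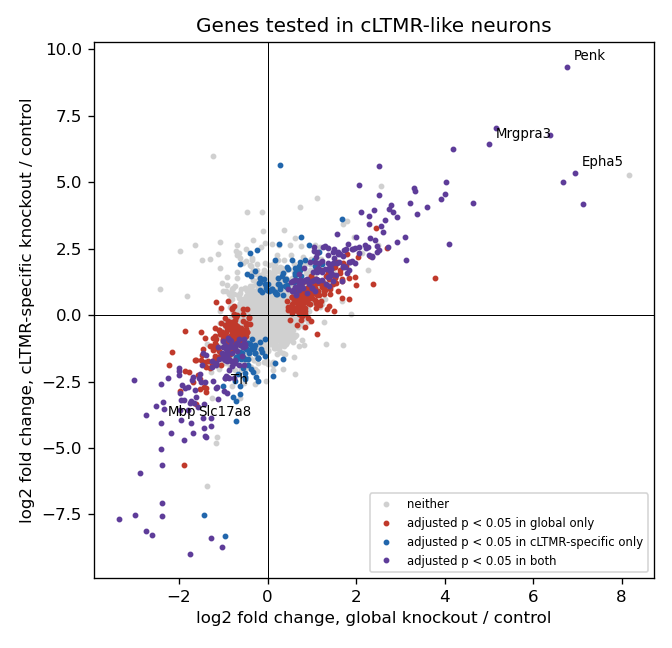
Log2 fold change of the 6601 genes tested in cLTMR-like neurons, global knockout (horizontal) against cLTMR-specific knockout (vertical), 1 point per gene, coloured by the arm in which it passed. The 268 genes passing in both lie in the upper right (146) and lower left (122).

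Mrgprd-type neurons, which are nonpeptidergic nociceptors, also differed between the global knockout and its control. Of 8760 genes, 114 passed, 53 higher and 61 lower. Tac1 averaged 1020 ± 234 CPM (n = 7) against 281 ± 55.2 CPM (n = 5), a log2 fold change of 1.84 ± 0.2 (adjusted p = 7.09e-08), and Calca 2150 ± 473 against 817 ± 279 CPM (1.38 ± 0.18). Marcks, a substrate of protein kinase C, rose by 2.83 ± 0.29. Pik3r1 (1.42 ± 0.2), Nrxn3, a presynaptic adhesion protein (1.44 ± 0.21), Alkal2, a ligand of the kinase ALK (2.02 ± 0.3), Kcnc4 (1.79 ± 0.29), Ddt (1.10 ± 0.19) and Hpcal1 (1.43 ± 0.25) rose as well. Esr1, the oestrogen receptor gene, had 147 UMIs against 3, a ratio of 19.2 with a counting interval of 6.43 to 94.0. The inducible Cre is a fusion with part of an oestrogen receptor. Kcnmb1, a subunit of the BK potassium channel, fell from 157 ± 40.8 to 25.5 ± 9.13 CPM (-2.64 ± 0.22, adjusted p = 2.24e-10). Rgs8 (-2.25 ± 0.26), the transcription factors Isl2 (-1.32 ± 0.16) and Hoxb5 (-1.89 ± 0.29), Nptxr (-1.36 ± 0.2), Clu (-1.66 ± 0.26), Sh2d4a (-3.42 ± 0.57), Plaur (-1.81 ± 0.32), Ctxn3 (-1.13 ± 0.2), Rgs10 (-0.97 ± 0.17) and the class marker Mrgprd (-1.26 ± 0.22) fell. Within runs 1 to 3 Tac1 differed by 2.12, 1.84 and 1.75, Calca by 1.32, 1.38 and 1.72, Marcks by 2.52, 2.01 and 2.96, and Kcnmb1 by -2.50, -2.54 and -2.41. With run as a block 258 genes passed, with male libraries alone 34, and without control replicate 2 there were 62.

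Of 20 lists, neuropeptides passed in Mrgprd-type neurons of the global knockout (adjusted p = 0.00313; adjusted p = 0.159 with an estimated correlation). Tac1, Calca, Bdnf (0.83 ± 0.22) and Cartpt (2.06 ± 0.55) rose among 7 tested, adjusted over the list alone, and 3 passed over all genes. Members of other lists that passed adjusted over the list alone included the channels Trpv1 (1.30 ± 0.29), Trpa1 (0.89 ± 0.23), Kcnk2 (2.26 ± 0.49) and Scn4b (-1.89 ± 0.43).

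The Cre of the cLTMR-specific knockout is meant to spare Mrgprd-type neurons, but where it acted was not measured. In this knockout edgeR called 0 of 8760 genes in Mrgprd-type neurons (240 at an unadjusted p under 0.05, 0 by DESeq2). With run as a block 25 genes passed there, with only the 2 groups compared 28, with no count filter 6 and without control replicate 2 there were 15. Control replicate 1 had 344, 349 and 171 of its 876 Mrgprd-type cells in clusters 18, 19 and 28. The knockouts had 244 and 78 cells in cluster 0 and 117 and 2 in cluster 12, and control replicate 2 had 136 and 16 in these. Tac1 stood at 0.01 ± 0.34, Calca at -0.04 ± 0.31, Marcks at 0.00 ± 0.45 and Kcnmb1 at -0.17 ± 0.35 (n = 2 each). Of the 114 genes, 47 (41.2%) kept their sign there. In other classes of the global arm, from the same mice, it was 64 of 79 tested in cLTMR-like neurons (81%, 38 called in both), 45 of 49 in Mrgpra3-type (91.8%), 37 of 47 in Sst/Nppb-type (78.7%) and 53 of 80 in peptidergic C neurons (66.2%). The difference between the arms itself passed for 6 genes (426 at an unadjusted p under 0.05), among them Kcnmb1, Marcks, Hoxb5 and Tac1. The arms also differ in the kind of Cre, tamoxifen, age and library run. The mitochondrially encoded list was called upward in this class (adjusted p = 0.0259; adjusted p = 0.897 with an estimated correlation).

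**Figure D3:**
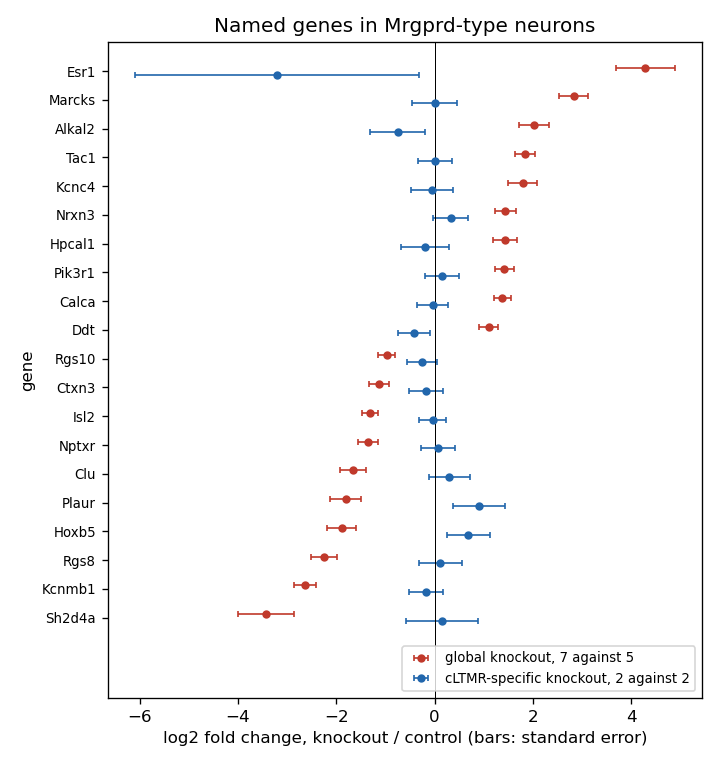
Log2 fold change with standard error of the 20 genes named by rule in Mrgprd-type neurons, in the global knockout (7 against 5 mice) and the cLTMR-specific knockout (2 against 2). Kcnmb1 lies at -2.64 and -0.17 and Tac1 at 1.84 and 0.01.

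In other classes few genes passed. In peptidergic C nociceptors of the global knockout 1 of 7234 genes passed, Esr1 (2.37 ± 0.43, adjusted p = 0.0268), which was also the 1 gene passing in myelinating Schwann cells (188 UMIs against 1, n = 3 each; 0 genes by DESeq2, 14 at an unadjusted p under 0.05). In peptidergic C nociceptors Esr1 did not pass with only the 2 groups compared, male libraries, the stricter cell filter, resolution 0.8 or 2.5, marker score, no gene left out of clustering or run 1 left out. It also did not pass there without any 1 of knockout replicates 1, 2, 4 and 7 and control replicates 1, 2 and 4, with log2 fold changes of 1.88 to 3.09 over the libraries left out. In Mrgpra3-type and Sst/Nppb-type neurons edgeR called 0 genes (116 and 92 at an unadjusted p under 0.05, and 0 by DESeq2 in each). Myelinated low-threshold mechanoreceptors had too few control libraries for a test in the global arm, but with called doublets kept they were tested and 5 genes passed, 1 higher and 4 lower. With at least 200 genes per cell 2 passed in them, both lower. In the cLTMR-specific knockout edgeR called 0 genes in Mrgpra3-type neurons, peptidergic C nociceptors, myelinated low-threshold mechanoreceptors and proprioceptors (95, 157, 27 and 79 at an unadjusted p under 0.05, and 0 by DESeq2). With run as a block 14, 3, 1 and 0 genes passed in these 4 classes with edgeR, and without control replicate 2 there were 17, 12, 15 and 14 (0, 0, 3 and 8 without knockout replicate 2). Marker score gave 12 in Mrgpra3-type neurons, and only the 2 groups compared gave 10 in myelinated low-threshold mechanoreceptors. There, 6 genes passed in peptidergic A-fibre nociceptors, including mt-Co3, Atpaf2 and mt-Rnr2, and 1 predicted gene in Sst/Nppb-type neurons, with 0 by DESeq2 in each. Without control replicate 2 these were 26 and 4, and in A-fibre nociceptors there were 16 without knockout replicate 2 and 2 without knockout replicate 1. Scn9a did not pass in any of these classes. Its log2 fold change ranged from 0.16 ± 0.22 in peptidergic C nociceptors to 0.41 ± 0.3 in Mrgpra3-type neurons of the global knockout.

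In Sst/Nppb-type neurons of the global knockout the nerve injury list (adjusted p = 1.26e-05) and the immediate early list (adjusted p = 0.00887) were called upward, each with adjusted p = 0.248 with an estimated correlation. The mitochondrially encoded list was called upward in peptidergic C (adjusted p = 0.000123; adjusted p = 0.682 with an estimated correlation) and A-fibre nociceptors (adjusted p = 0.000211; adjusted p = 0.991 with an estimated correlation) of the cLTMR-specific knockout. It was called downward in Schwann cells of the global knockout (adjusted p = 0.00381; adjusted p = 0.205 with an estimated correlation).

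Over all neurons pooled, 71 of 12054 genes passed in the global knockout, 15 higher and 56 lower. With run as a block 248 passed (90 higher, 158 lower), in runs 1 to 3 with that block 431 (179 and 252) and with male libraries 5, all lower. Without control replicates 1, 2, 4 and 5 in turn there were 31, 35, 35 and 45, and without knockout replicate 4 there were 37. Epha5 (1.22 ± 0.22), Igfbp3 (1.43 ± 0.27) and Kcnc4 (1.32 ± 0.24) were among those higher. Rgs8 (-1.91 ± 0.21), C1ql4 (-3.64 ± 0.47) and Id4 (-1.01 ± 0.14) were among those lower. Over all neurons 4 lists were called in the global knockout and 2 in the cLTMR-specific knockout, and 0 in each with an estimated correlation. In the cLTMR-specific knockout edgeR called 0 (259 at an unadjusted p under 0.05, 3 by DESeq2). The sex by genotype test in the global arm called 0 genes in cLTMR-like, Mrgprd-type and peptidergic C neurons and in all neurons with edgeR (152, 192, 197 and 245 at an unadjusted p under 0.05), and DESeq2 was not run for it. All female libraries of that arm were in run 3 and all male ones in other runs, so this test cannot tell sex from run.

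Class shares did not differ detectably. cLTMR-like neurons made up 16.8% ± 7.0 of neurons in the global knockout (n = 7) and 20.2% ± 9.89 in control (n = 5), exact permutation p = 0.501. Mrgprd-type neurons made up 25.1% ± 6.85 and 32.9% ± 11.3 (exact permutation p = 0.183). Leaving out 1 library, that difference of -7.83 points ranged from -10.9 to -3.69. In the cLTMR-specific arm the cLTMR-like share was 20.2% ± 10.7 and 17.3% ± 6.98 (n = 2 each). By exact permutation 0 of 10 classes among neurons and 0 of 16 among all cells passed after adjustment.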

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

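The tests of the explanations for every pattern in this part were chosen after the results were seen.

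In cLTMR-like neurons Penk and many other genes differed in both knockouts, and library run as the whole cause is argued against by the 925 genes called in the global arm with run as a block. Intact cells of another class carrying the cLTMR name would bring its abundant genes, but the 30 genes most enriched in a class and not used for naming reached at most a median of 12.1% of its level in knockout cells of clusters 4 and 16 (Mrgprd-type, quartiles 4.39 and 37.5). Their cLTMR counterparts stood at 50.6% of control and the cLTMR markers at 34.1% (5.56 to 92.1), so cells of another class that had lost its genes are not excluded. Free Penk RNA would reach all classes alike, but 0.354% of thinned Mrgprd-type neurons of the global knockout had a Penk UMI, against 15.2% of cLTMR-like neurons. Loss of Nav1.7, the biological difference the design names, stays open as a hypothesis. The 2 arms had different kinds of Cre, but in each arm every Cre-positive mouse was a knockout and every control lacked Cre. Loss of Nav1.7 therefore cannot be told apart from an effect of Cre.

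In Mrgprd-type neurons of the global knockout, library run as the whole cause is argued against by the 258 genes called with run as a block. Peptidergic cells or their free RNA would raise all abundant peptidergic genes alike. The other 28 genes of that set gained a median of 1.44% of their peptidergic level (quartiles -0.157 and 6.36), while Calca and Tac1 would need 17.2% and 16.0%. Loss of Nav1.7 in these neurons may be the cause. In the cLTMR-specific knockout, where this class is meant to keep the gene, 41.2% of the called genes had the same sign. In 4 other classes of the global knockout 66.2% to 91.8% had it. Those classes came from the same libraries, so differences shared within a library could alone give such shares. Loss of Nav1.7 cannot be told apart from active CreER or another effect shared by cells of the same mice, because every CreER-positive mouse was a knockout.

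Th and Gm7271 were picked out because the test of the difference between the knockouts passed in cLTMR-like neurons, with 1.88 for Th and 1.79 for Gm7271 (global minus cLTMR-specific, log2, adjusted p = 0.0068 each). A mixture in which part of the global knockout's cells kept the control profile might lessen the fall of Th. Within clusters 4 and 16, which hold most of the class in both knockouts, Th still differed by 2.41 (413 ± 60.5 against 79.2 ± 32.2 unscaled CPM), which argues against that mixture as the whole cause. With run as a block in place of sex, Th differed by 1.84 (edgeR adjusted p = 9.37e-05). Within run 4 and clusters 4 and 16, Th was 326 and 375 unscaled CPM in global knockout replicates 6 and 7. It was 102 and 56.5 in the cLTMR-specific knockouts of the same run. These values argue against library run as the whole cause for Th, though run 4 held no global control. The arms also differ in age and Cre, and these stay open as untested, as does run for Gm7271.

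In Mrgprd-type neurons the same kind of test picked out Gm45052 (-3.96), Kcnmb1 (-2.46), Gm16364 (-2.47), Marcks (2.83), Hoxb5 (-2.58) and Tac1 (1.83), as global minus cLTMR-specific log2 fold changes.

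Single libraries lay far from the others of their group in 8 of 40 groups tested, where chance alone picks out about 1 in 20. The highest Penk level in peptidergic C nociceptors, TMM-scaled, was 28.8 CPM in the global knockout and 11.2 CPM in its control. The lowest share of Mrgprd-type neurons in the global knockout was 10.0%. The highest share of cLTMR-like neurons was 32.0% in the global knockout and 37.4% in its control. The highest unnamed share in the global knockout was 53.9%. The highest median depth was 20800 UMIs per neuron in the global knockout and 19200 in its control. These outliers are not independent of each other. The highest cLTMR-like shares and depths were those of replicate 1 of each group. The 10.0% and the 53.9% were both global knockout replicate 5, with 184 neurons in unnamed cluster 29, whose best candidate name was the Mrgprd-type.

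Other splits of the global-arm libraries were fitted alike without run, 100 per class, the real one included, with shares not adjusted over the counts tested. For the 584 genes in cLTMR-like neurons 1 of 100 splits, the real one, gave as many (highest other 178), which argues against chance. For the 7 lists there with the preset correlation 4 of 100 did, and another split gave 9, so chance is not excluded. An estimated correlation, under which 3 of the 7 were called, was not run on the splits to test chance. Nor is it excluded for the 114 genes in Mrgprd-type neurons (3 of 100, highest other 226) and the 71 genes over all neurons (3 of 100, highest other 639), where other splits gave more. The 178 and the 226 came from the same split, which set all global controls and knockout replicates 2 and 3 against the other knockouts. The split with 639 set run 2 and knockout replicate 5 against the rest, which points to a structure of the samples, and with run as a block 248 genes were called over all neurons. The same split gave the 256 genes that were the highest other value in peptidergic C nociceptors.

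Chance cannot be excluded for 4 other counts. As many lists were called in 53 of 100 splits in Mrgprd-type neurons (real 1, highest other 8) and in 44 over all neurons (real 4, highest other 9). In peptidergic C nociceptors 16 splits gave as many genes as the real 1, and in Sst/Nppb-type neurons 38 as many lists as the real 2 (highest other 6). In Schwann cells the 10 splits are too few for a share under 0.05, with 1 gene (7 splits, highest other 44) and 1 list (5 splits, highest other 2). Where the real count was 0, all 100 splits give as many by construction, which tests nothing. This covers lists in peptidergic C nociceptors (highest other 6), genes and lists in Mrgpra3-type neurons (29 and 1) and genes in Sst/Nppb-type neurons (25).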

How the results depend on the processing

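Among the alternatives, 4 were chosen after seeing the data: recurring barcodes left out, at least 200 genes per cell, highest doublet scores left out, and run 1 left out. The cause of each change given here was not tested, apart from fewer libraries or cells where the setting names them. No paired analysis was possible because the labels carry no replicate numbers shared by the groups. The stricter cell filter gave no value for single classes of the cLTMR-specific arm, and male libraries alone and runs 1 to 3 alone gave values for the global arm only. Where leaving out a library left 1 sample in a group, that sample was assumed to vary like the other groups.

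Penk in cLTMR-like neurons passed under every alternative run, at 6.52 to 7.00 (6.54 to 6.94 leaving out 1 library) in the global and 6.88 to 9.63 (7.27 to 9.75) in the cLTMR-specific knockout. Its difference from other neurons was 4.69 to 7.94 (5.63 to 7.70). Over all neurons of the cLTMR-specific knockout it passed only in a fit of the 2 groups compared (3.79, adjusted p = 5.46e-05).

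Of 90 results for named genes, 2472 alternative values kept the direction and side of the threshold in 2342 cases, lost the threshold in 127 (23 with male libraries only) and reversed in 3. The 3 were Calca in cLTMR-like neurons of the cLTMR-specific knockout, at 0.16 by marker score, 0.28 without the highest doublet scores and 0.20 without cLTMR-specific knockout replicate 1 (range over libraries left out -0.44 to 0.20). Scn9a reversed over all neurons of the global knockout in runs 1 to 3 (-0.01), and its difference between cLTMR-like and other neurons reversed without knockout replicates 1 (-0.02) and 3 (-0.02) and controls 3 (-0.04) and 4 (-0.01), range -0.04 to 0.10. Without control 1 the cLTMR-like share differed by 0.925 points (range -5.91 to 0.925).

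With run as a block the counts of changed genes were 925 (cLTMR-like), 258 (Mrgprd-type), 248 (all neurons) and 6 (other classes) in the global and 816, 16 (all neurons) and 60 (other classes, which in this arm include the Mrgprd-type with 25) in the cLTMR-specific knockout, and 41 for the difference between them. Runs 1 to 3 gave 954, 383, 431 and 10 in the global knockout, male libraries alone 367, 34, 5 and 0, and the stricter cell filter 386 (cLTMR-like), 34 (all neurons) and 0 (other classes). Run 1 left out gave 67 (Mrgprd-type), 32 (all neurons), 0 (other classes) and 9 (difference). DESeq2's Wald test gave 138 and 3 over all neurons in the 2 arms, 0 in other classes of the cLTMR-specific knockout and 6 for the difference. No count filter gave 111 (all neurons) and 6 (other classes) in the global knockout, 24 (other classes) in the cLTMR-specific knockout, 48 for the difference, 12 for sex by genotype and 7 lists in cLTMR-like neurons of the cLTMR-specific knockout. Only the 2 groups compared gave 0 (other classes, global), 10 (all neurons) and 42 (other classes) in the cLTMR-specific knockout. Marker score gave 6 (other classes, global), 150 and 12 in the cLTMR-specific knockout and 0 for the difference. With no gene left out of clustering other classes gave 0 in the global and 4 in the cLTMR-specific knockout. Other classes of the latter gave 21 with DESeq2 size factors, 3 with no sex term, 0 with at least 20 cells, 2 at resolution 0.8, 0 with at least 200 genes (4 for the difference) and 4 without the highest doublet scores. An estimated correlation left 3 and 2 lists in cLTMR-like neurons of the 2 arms, and 0 in Mrgprd-type neurons and over all neurons.

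Leaving out 1 library gave 445 to 595 genes in cLTMR-like and 62 to 126 in Mrgprd-type neurons of the global knockout (62 without control 2). Over all neurons it gave 31 to 80 (31 without control 1, 35 without control 2, 37 without knockout 4, 35 without control 4, 45 without control 5), and in other classes 0 to 1 (0 without knockouts 1, 2, 4 and 7 and controls 2 and 4). In the cLTMR-specific knockout it gave 113 to 383 (113 without knockout 1, 235 without knockout 2, 132 without control 1), 0 to 3 over all neurons (3 without control 2) and 2 to 103 in other classes (2 without knockout 1, 27 without knockout 2, 4 without control 1, 103 without control 2). The difference between the knockouts gave 0 to 19 genes (5 without global knockout 1, 4 without global knockout 5, 1 without cLTMR-specific control 1, 19 without its control 2, 0 without its knockout 2). Lists in cLTMR-like neurons numbered 5 to 9 and 3 to 7 (7 without cLTMR-specific control 2). Cells with a Penk UMI made up 27.6% at 1500 UMIs and 40.8% unthinned in the global knockout, and cells with a Scn9a UMI 38.6% and 58.0%, or 46.4% and 37.2% in the cLTMR-specific knockout.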

Other observations

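The tests of the hypotheses in this part were all chosen after the results were seen. Neurons of the cold-sensing Trpm8 class, found in too few libraries for the gene tests, carried Penk in control mice. In unscaled CPM it stood at 1070 ± 214 CPM in the global control (n = 2), 215 ± 200 CPM in the global knockout (n = 5), 36.8 CPM in the cLTMR-specific knockout (n = 1) and 212 ± 115 CPM in its control (n = 2). Those neurons numbered 61, 225, 62 and 196 cells.

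Esr1 was higher in the global knockout in 6 of 6 classes compared, those with at least 3 libraries in each group (cLTMR-like, Mrgprd-type, Mrgpra3-type, Sst/Nppb-type, peptidergic C and Schwann). Among classes with fewer, myelinated low-threshold mechanoreceptors went the other way, at 37.8 unscaled CPM in the knockout (n = 5) against 218 in control (n = 2, 4 UMIs). In Mrgprd-type neurons its lowest knockout library (12.3 CPM, unscaled) lay above its highest control (2.2 CPM). A candidate explanation is that the CreER transgene carries Esr1 sequence, which would raise it in every class, as in these 6. Loss of Nav1.7 within the cell as the whole cause is argued against by non-neuronal cells, where Scn9a averaged 3.67 unscaled CPM in the global control against 244 in neurons. In them Esr1 stood at 190, 91.9, 88.5 and 39.6 CPM in 4 global knockout libraries and at 3.68, 0 and 37.1 CPM in 3 controls (exact permutation p = 0.0286, the smallest the splits can give). The nearest of these, 39.6 and 37.1, rest on 2 UMIs and 1 UMI. cLTMR-like cells of the cLTMR-specific knockout held 1 Esr1 UMI, where the rate of the global knockout gives 7.56. That comparison alone leaves the matter open, since single global knockout libraries ranged from 0 to 31.9 CPM. Reads would be needed to tell transgene from gene.

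cLTMR-like cells of the global knockout fell in both kinds of cluster. In the control-rich clusters, with recurring barcodes left out, 0.461% of 217 thinned cells had a Penk UMI (exact interval 0.0117 to 2.54), against 19.8% (17.2 to 22.5) in clusters 4 and 16 and 0.714% of control cells. Penk was left out of the clustering, but many genes that changed with it were used. A low Penk share in the control-rich clusters was therefore largely fixed in advance. Whether part of the cells kept the control profile stays open. The mice were uneven in their share of such cells. The control-rich clusters held 143 of 374 cLTMR-like cells of replicate 6 (85 with recurring barcodes left out), 55 of 268 of replicate 7 and 43 of 147 of replicate 1, but 2 of 88 of replicate 2. Whether Scn9a was intact in them was not tested, as 3' counts cannot show the deletion.

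In global knockout replicate 6, 773 of 2997 barcodes recurred in cLTMR-specific control replicate 1, where the highest other pair of libraries shared 6. The 692 of its 2759 kept cells with such a barcode held 150 of the library's 151 Xist UMIs, 9.2% of its UMIs and 59 of its 374 cLTMR-like cells. Barcode prefixes were shared to 73.08% to 100% within runs 1 to 3 or within run 4, and to 20.61% to 28.47% between them, although the labels name 1 kit for all.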
